A study of Mus musculus with 8 samples.

How the data were processed

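The data are 8 libraries from the cortex of 4 mice, a cleared-lysate input and an HA IP library per animal. Per the labels' protocols, precipitated RNA was cleared of DNA and purified on columns, its integrity was checked on a Bioanalyzer, and paired-end stranded libraries were made from 100 ng of RNA with selection for mRNA. The labels state that male and female animals were used without saying which was which. The submitters' processing notes name bcl2fastq 2.17, STAR, HTSeq and the mouse genome build mm10. Versions of STAR and HTSeq, the annotation and the strand setting of the counting are not given in the sources used here. Each deposited file holds 1 value for each of 24060 gene symbols, and neither the labels nor the file headers name its unit. The values were read as FPKM as deposited by the authors (fragments scaled to gene length and library size). The reason was that, with 1 whole length fitted per gene and 1 whole total per library, all 142235 values above 0 came within 0.001 of a whole number of fragments. Lengths were chosen to meet that tolerance, so this bears on the unit mainly through genes with values above 0 in many libraries.

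From these steps the number of fragments behind each value was recovered for all 20045 genes with a value above 0. The recovered fragments made up 99.91% to 99.96% of the totals implied by the steps, which were 33834388 to 53625125. The library totals came out at most 0.00154 from a whole number, 2 of them further than 0.001, and were rounded. On 4000 simulated genes, none as long as the longest lengths fitted here, the recovery gave exact counts for 99.5% of the genes. For 348 of 14466 genes with at least 100 fragments the length in the FPKM exceeded the whole genomic span of the gene in RefSeq. Plec, for example, had a length of 224542 bases in the steps against a span of 60405 bases. Those lengths are not lengths of single transcripts, so FPKM levels of different genes are not compared here. The length cancels in a gene's ratio of FPKM, but a long length lowers the FPKM, so the pseudocount shrinks the fitted fold change of such a gene more. The files hold 27 rows whose gene symbols had become spreadsheet dates, 4 of them under a repeated name. These rows stayed in the tests and are not named.

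A test for raw counts had been planned and was not used, because the deposited values were FPKM. It was not run on the recovered fragments either. The test used instead was limma 3.58.1 in R 4.3.3, on log2(FPKM + 0.1) with an intensity trend, comparing HA IP with input without further covariates. FPKM were first divided by trimmed mean of M-values (TMM) factors, computed per library with 0.3 of the M-values and 0.05 of the A-values trimmed at either end and no weights. Genes were tested if at least 4 libraries had at least 0.246 CPM (recovered fragments scaled to library size), equal to 10 fragments in a library of median size, and if all libraries together had at least 15, which left 15605 genes. The TMM factors and this filter were computed with code written out for this purpose, not with a package. The p-values are two-sided and Benjamini-Hochberg adjusted over all genes tested, with a threshold of 0.05. A pseudocount of 0.1 FPKM makes fold changes of low genes smaller than they are. Values are given as FPKM on the deposited scale, while fold changes are after TMM scaling, with SE from the limma fit. That fit leaves out the pairing of libraries by animal, so the SE include differences between animals that both libraries of an animal share.

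Before the data were examined, 35 gene lists were fixed from textbook knowledge, covering markers of astrocytes and of the other cell types of cortex, astrocyte and neuronal functions, and RNA classes. Of their 1044 entries 1038 matched a row, 2 of them by an older or newer name. The 33 lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 33 lists. The lists of blood cell markers and of mitochondrially encoded genes had too few tested members and were not analysed here. Named genes were chosen by a rule fixed at the same time. The rule takes Aldh1l1 and Rpl22; the 12 largest rises and 12 largest falls among genes past the threshold with a mean of at least 5 CPM and the same direction in all 4 animals; the 10 genes with the most fragments in HA IP; and, for each list, its preset examples and up to 3 members called against the direction of most called members. It took 178 genes, some of which are not reported here, and those whose call changed when a library was left out are given with the dependence on the processing. The design and most alternatives were also fixed before the data were examined, and alternatives added later are identified as such.

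Libraries of the same animal number deviated together. The correlation of deviations from the group means was 0.22 to 0.40 for the 4 same-number pairs and at most 0.11 for the others, so the numbers, which mark 1 animal each, pair the libraries. Xist and 4 Y-linked genes were read for the same purpose. Xist had 6637 and 8533 fragments in the input and HA IP of animal 595 and at most 13 in any other library, and input and HA IP of each number matched, although these genes separate only animal 595 from the others. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 13.2 at the lowest, so none was treated as a duplicate.

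Alternatives were median-of-ratios scaling, no scaling beyond the deposited FPKM, no filter on low counts, a filter of 1 CPM in 4 libraries, limma-voom on the recovered fragments, the animal as a block, thinning to the smallest library, leaving out each animal and each library, pseudocounts of 0.01 and 1, limma's treat against a fold of 1.5, removal of a length trend, camera with an estimated correlation, and fry. The path from filter to test was tested on simulated data with 200 changed genes and the real library sizes. For HA IP against input, 56.7% of 67 genes changed by 1.5-fold, 98.5% of 66 changed by 2-fold and all of 66 changed by 4-fold were recovered on the right side, among 15972 genes tested. Of the calls, 6.59% were unchanged genes, and 0 genes were called when no gene was changed. A simulated list of 40 genes changed by 1.3-fold was called, and 0 of 50 unchanged lists were. The simulation changed few genes, up and down in similar numbers, and drew genes independently with the same dispersion. In the real data most tested genes were called and members of lists were correlated. The simulated rates therefore do not measure the error of the scaling, of the gene calls or of the list tests there. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 read the files, and matplotlib 3.10.9 drew the plots.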

Results

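Messenger RNA was sequenced from the cortex of 4 young adult mice, aged about 80 postnatal days, that carried a tamoxifen-inducible Cre recombinase driven by Aldh1l1 and the RiboTag allele. RiboTag is a Cre-dependent version of the ribosomal protein gene Rpl22 that puts a hemagglutinin (HA) tag on ribosomes of recombined cells. Each animal gave 2 libraries, an input library from the cleared cortex lysate and an HA IP library from RNA bound to ribosomes precipitated through the tag. There were thus 4 input and 4 HA IP libraries, named here by the animal numbers 579, 580, 581 and 595. The libraries held 33834388 to 53625125 fragments, recovered from the deposited values. The lowest total was that of the HA IP library and the highest that of the input library of animal 595. A value above 0 was found for 16948 ± 90.2 genes in HA IP and 18611 ± 299 genes in input. The comparison of HA IP with input asked which transcripts the tagged ribosomes carried, and how selectively these were transcripts of astrocytes.

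Astrocyte transcripts were enriched in HA IP. Aldh1l1, the folate-metabolism enzyme gene whose regulatory sequence drives the Cre, stood at 406 ± 26.2 FPKM in HA IP and 21.8 ± 0.926 FPKM in input (deposited scale, SD, n = 4 each). Its log2 fold change was 5.05 (SE 0.08). All 49 tested astrocyte markers rose, with log2 fold changes from 1.92 to 5.39 and a median of 4.23. The list median lay between 4.18 and 4.28 in the 4 animals (camera, adjusted p = 1.2e-16; adjusted p = 0.0437 with an estimated correlation). The gap junction gene Gja1 changed by 4.18 (SE 0.13), the glutamate transporter gene Slc1a2 by 3.51 (SE 0.10) and the water channel gene Aqp4 by 2.97 (SE 0.12). Rpl22, the gene that carries the tag, had a log2 fold change of 0.69 (SE 0.13) after TMM scaling, but its deposited FPKM was lower in HA IP than in input in 3 of 4 animals, and on that scale it had -0.14 and did not pass.

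**Figure D1:**
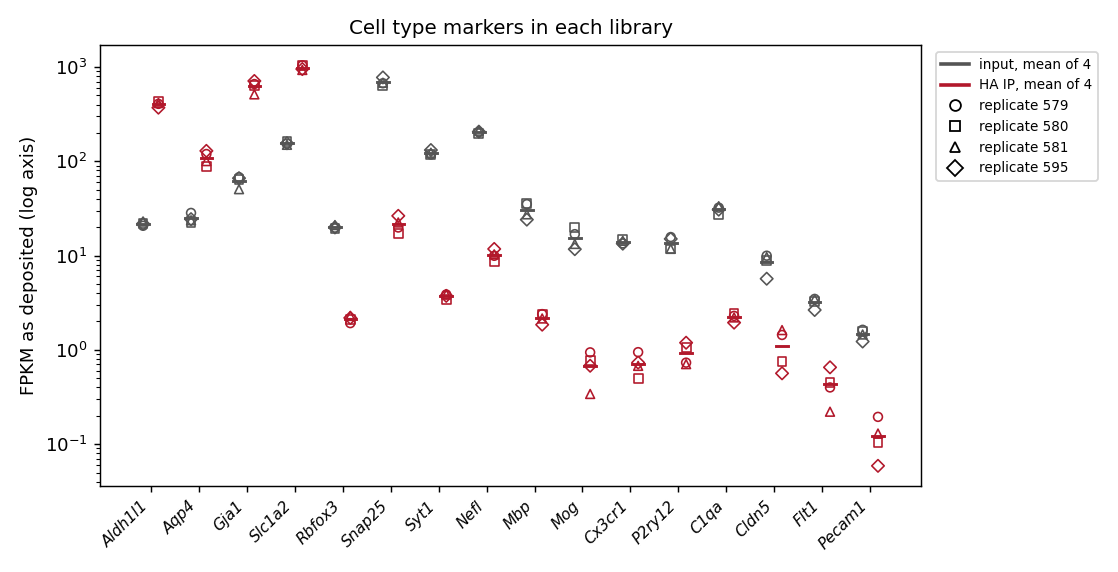
FPKM as deposited (vertical log axis) of 16 marker genes of astrocytes, neurons, oligodendrocytes, microglia and endothelium in each of 4 input (grey) and 4 HA IP (red) libraries, with a symbol per animal and a bar at the mean. Aldh1l1, for example, averaged 406 in HA IP and 21.8 in input, while Snap25 averaged 21.5 in HA IP and 689 in input.

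Among the 12 largest rises were Apoe, the main lipid carrier of the brain, at 5.39 (SE 0.23), and Phgdh, the first enzyme of serine synthesis, at 5.22 (SE 0.15). They also included Aldoc, the brain aldolase, at 5.11 (SE 0.16), Pla2g7 at 5.12 (SE 0.11) and Acsbg1 at 5.02 (SE 0.09), with Mfge8 as the smallest of the 12. Btbd17, Myoc, Tst and Pbxip1 rose by 5.33, 5.30, 5.27 and 5.02, and so did the tubulin gene Tubb2b by 5.10, whose reads can be shared with its near-identical paralogs. Among the 12 largest falls, the first was the potassium channel gene Kcnk9, at 0.144 ± 0.0564 FPKM in HA IP and 20.6 ± 2.21 FPKM in input, a log2 fold change of -5.75 (SE 0.18). Genes of neuronal receptors and their partners were also there: Nptxr at -5.36 (SE 0.15), the NMDA receptor gene Grin2a at -5.12 (SE 0.14) and the serotonin receptor gene Htr2a at -5.08 (SE 0.13). Synpr, Xkr4, Erbb4, Lrrc8b, Gpr26, Nos1 and Rapgef5 changed by -4.93 to -4.82. The 10 transcripts with the most fragments in HA IP included Apoe, Slc1a2, Glul, Cpe, Rn45s, Sparcl1, Aldoc, Scd2 and Clu. In each library the 10 leading genes together took 15.7% to 18.1% of all fragments in HA IP and 3.63% to 4.26% in input, and Apoe alone took 2.56 ± 0.147% and 0.110 ± 0.0111%. Rn45s, the ribosomal RNA precursor, took 1.47 ± 0.741% of the fragments in HA IP, with the highest share, 2.55%, in animal 595, and 0.715 ± 0.332% in input.

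Of 15605 genes tested, 6573 were higher and 6413 lower in HA IP (limma, adjusted p under 0.05), and 3992 and 4239 of these differed by at least 2-fold. Spearman correlations over genes ran from 0.982 to 0.993 among HA IP libraries, from 0.990 to 0.996 among inputs and from 0.780 to 0.813 between the groups. The first principal component held 92.2% of the variance and separated HA IP from input. The split into higher and lower depends on the scaling. TMM scaling raised every log2 ratio of HA IP to input by 0.84 over the deposited FPKM, and the median log2 fold change was 0.01 with it and -0.75 without it. On the deposited scale 3643 genes were higher and 9613 lower, so the higher calls made up 27.5% of all calls in place of 50.6%. A gene with a log2 fold change between 0 and 0.84 here is lower in HA IP on the deposited scale, up to the effect of the pseudocount, and this is stated where such a gene is named.

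**Figure D2:**
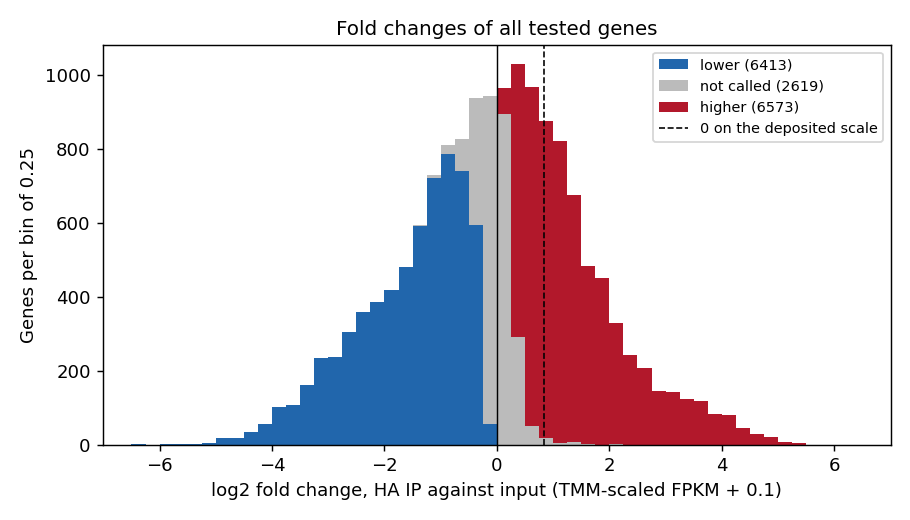
Number of genes (vertical axis, bins of 0.25) by log2 fold change of HA IP against input (horizontal axis, limma on TMM-scaled FPKM), for the 15605 genes tested. The 6413 genes called lower are blue, the 6573 called higher red and the 2619 not called grey, and the dashed line at 0.84 marks equal deposited FPKM.

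Neuronal transcripts fell. All 30 pan-neuronal markers were lower in HA IP, with a median log2 fold change of -2.99 and medians between -3.06 and -2.94 in the 4 animals (camera, adjusted p = 7.3e-12; adjusted p = 0.0437 with an estimated correlation). Snap25, a SNARE protein gene of synaptic vesicle fusion, went from 689 ± 61.4 FPKM in input to 21.5 ± 3.90 FPKM in HA IP, and Syt1, the calcium sensor of release, from 122 ± 6.56 to 3.73 ± 0.204. Rbfox3, which encodes the neuronal nuclear antigen NeuN, changed by -2.35 (SE 0.08) and the neurofilament gene Nefl by -3.48 (SE 0.08). Of 20 excitatory neuron markers, 18 fell and 2 rose, with a median of -3.49 (camera, adjusted p = 2.6e-06). With an estimated correlation this list did not pass (adjusted p = 0.0703). The vesicular glutamate transporter gene Slc17a7 changed by -3.67 (SE 0.13) and Camk2a by -3.53 (SE 0.11). The members that went the other way were the nuclear receptor gene Rorb at 2.34 (SE 0.13), which stands in the astroglial transcription factor list too, and Fezf2 at 0.39 (SE 0.09), which reverses to -0.45 on the deposited scale. Of 24 inhibitory neuron markers, 22 fell and 2 rose, with a median of -3.09 (camera, adjusted p = 3.2e-06; adjusted p = 0.0364 with an estimated correlation). Gad1 and Gad2, the GABA-synthesising enzymes, changed by -4.07 (SE 0.13) and -4.41 (SE 0.21), Pvalb by -4.17 (SE 0.15) and Sst by -4.07 (SE 0.17). The transcription factor gene Sox6 was among the members that rose, by 1.53 (SE 0.12).

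Genes of synapses and excitability were mostly lower too. Of 36 synaptic vesicle and presynaptic genes, 34 fell and 2 rose, with a median of -3.13 (camera, adjusted p = 2.2e-11; adjusted p = 0.0437 with an estimated correlation). Bsn, a scaffold of the active zone, changed by -3.31 (SE 0.13), and Vamp2 by -1.22 (SE 0.09). The exceptions, Unc13c at 0.78 (SE 0.14) and Sypl at 0.75 (SE 0.11), were -0.05 and -0.07 on the deposited scale and passed no test there. Of 40 postsynaptic and glutamate receptor genes, 35 fell, 4 rose and 1 did not pass, with a median of -2.28 (camera, adjusted p = 8.3e-08; adjusted p = 0.129 with an estimated correlation). Grin1, the obligatory NMDA receptor subunit gene, changed by -2.97 (SE 0.13) and the scaffold gene Dlg4 by -2.30 (SE 0.08), whereas the NMDA receptor subunit gene Grin2c rose by 3.92 (SE 0.11) and Homer3 by 2.95 (SE 0.13). Gria1, an AMPA receptor subunit gene, changed by -0.80 (SE 0.13). On the deposited scale 2 members rose and 37 fell. Of 31 voltage-gated sodium and potassium channel genes, 30 fell and none rose, with a median of -3.20 (camera, adjusted p = 8.6e-11; adjusted p = 0.0434 with an estimated correlation); Scn1a changed by -4.31 (SE 0.26) and Scn2a1 by -3.57 (SE 0.15). These 3 lists hold 9, 2 and 1 genes that also stand in other lists, the 9 all in the neuronal marker lists, so they are not independent of these. Of 17 immediate early genes, 12 fell, 1 rose and 4 did not pass, with a median of -2.44 (camera, adjusted p = 0.00512). That call was lost with an estimated correlation (adjusted p = 0.354) and on the deposited scale (adjusted p = 0.0533). Egr1 changed by -3.52 (SE 0.26) and Arc by -3.33 (SE 0.51), while Fos had -0.48 (SE 0.59) and did not pass. Jun was the member that rose, by 1.45 (SE 0.30); without the scaling it had 0.61 and did not pass.

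Markers of other glia and of vessels were mostly lower, with exceptions. All 24 microglia markers fell, by a median of -2.95 (camera, adjusted p = 5.8e-08; adjusted p = 0.0121 with an estimated correlation), for example the chemokine receptor gene Cx3cr1 by -3.35 (SE 0.16) and the complement gene C1qa by -2.91 (SE 0.10). Of 27 oligodendrocyte markers, 22 fell, 4 rose and 1 did not pass, with a median of -2.57 (camera, adjusted p = 1.1e-04; adjusted p = 0.268 with an estimated correlation). The myelin protein genes Mbp and Mog changed by -2.90 (SE 0.14) and -3.56 (SE 0.28). In the opposite direction, Gsn, which encodes the actin-severing protein gelsolin, rose by 2.45 (SE 0.22), the myelin enzyme gene Cnp by 2.24 (SE 0.12) and Gpr37 by 1.42 (SE 0.11). Of 17 oligodendrocyte precursor markers, 11 fell, 4 rose and 2 did not pass, and the list did not pass as a set (median -0.82; camera, adjusted p = 0.0738). The growth factor receptor gene Pdgfra changed by -2.68 (SE 0.24), against rises of Tmem100 by 3.29 (SE 0.09), Olig1 by 2.68 (SE 0.13) and Olig2 by 2.33 (SE 0.34). Of 22 endothelial markers, 20 fell, 1 rose and 1 did not pass, with a median of -2.05 (camera, adjusted p = 9.5e-05; adjusted p = 0.118 with an estimated correlation). Cldn5 and Pecam1, genes of endothelial junctions, changed by -2.13 (SE 0.31) and -2.22 (SE 0.21), and the lipid transporter gene Mfsd2a rose by 4.08 (SE 0.19), from 8.17 ± 1.64 to 78.8 ± 19.8 FPKM.

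The remaining cell type lists, including that of progenitors and immature neurons, gave no call as sets. Their medians differed between animals, least in the progenitor and immature neuron list (0.52 to 0.88). Of 15 mural cell markers, 8 fell, 2 rose and 5 did not pass (median -0.77; camera, adjusted p = 0.151). Rgs5, a pericyte gene, changed by -2.52 (SE 0.26), while Pdgfrb rose by 2.38 (SE 0.12) and Notch3 by 2.14 (SE 0.18). The mural median was 0.02 in animal 595 and between -1.22 and -0.78 in the other animals. Taken member by member, however, the median log2 difference of animal 595 from the others was 0.02 in HA IP and -0.07 in input. The higher list median therefore does not show a shift of the list as a whole. Of 15 fibroblast and meningeal markers, 5 rose, 3 fell and 7 did not pass (camera, adjusted p = 0.819). The median was -0.16, opposite in sign to the mean of 0.27 and to the test, and ran from -0.79 in animal 581 to 1.11 in animal 595. The counts depended on the setting, with 3 higher and 6 lower on the deposited scale, 3 and 4 without animal 595, and 3 and 3 without animal 580. Mgp, an inhibitor of calcification, changed by -3.00 (SE 0.21) and the proteoglycan gene Lum by -1.34 (SE 0.34). Of 11 ependymal and choroid plexus markers, 5 rose (4 adjusted over the list alone), 3 fell and 3 did not pass (median 0.98; camera, adjusted p = 0.627). The numbers were 3 and 3 on the deposited scale and without animal 580 or 595 or the input of either, and 4 and 1 with a filter of 1 CPM. Foxj1, the master gene of motile cilia, rose by 1.72 (SE 0.21), and Ccdc153 fell by 1.58 on the log2 scale (SE 0.23). Of 14 progenitor and immature neuron markers, 8 rose, 4 fell and 2 did not pass (median 0.83, or 0.04 on the deposited scale, where 5 rose and 4 fell; camera, adjusted p = 0.248). Sox2, which stands in the astroglial transcription factor list too, rose by 3.81 (SE 0.09), and Dcx, a microtubule protein gene of migrating neurons, changed by -2.32 (SE 0.22).

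**Figure D3:**
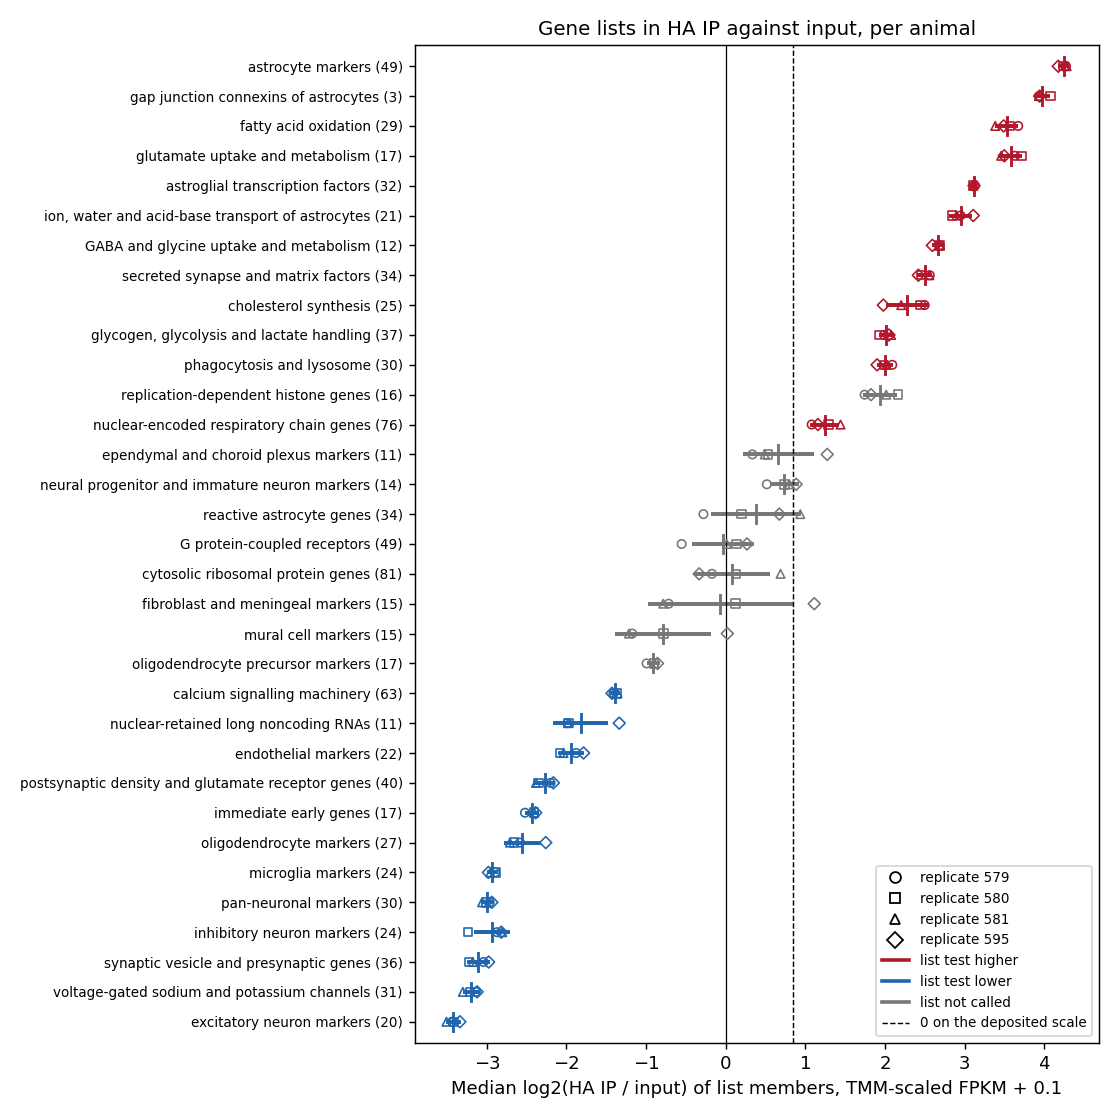
Median log2 ratio of HA IP to input over the members of each of 33 gene lists (horizontal axis, TMM-scaled FPKM), with a symbol for each of 4 animals, a tick at their mean and a bar of 1 SD either side; numbers in brackets are genes tested, and red, blue and grey mark lists called higher, lower and not called by camera. Astrocyte markers lay between 4.18 and 4.28 and pan-neuronal markers between -3.06 and -2.94, while the fibroblast and meningeal list ran from -0.79 to 1.11; the dashed line at 0.84 marks where a ratio of deposited FPKM would be about 1.

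Genes for what astrocytes take up and buffer were higher in HA IP. Of 17 glutamate uptake and metabolism genes, 14 rose and 3 fell, with a median of 3.55 (camera, adjusted p = 3.7e-04; adjusted p = 0.124 with an estimated correlation). Glul, the glutamine synthetase gene, went from 537 ± 57.9 to 7611 ± 1015 FPKM and the transporter gene Slc1a3 from 139 ± 6.50 to 1009 ± 31.2. The genes that fell were the mitochondrial glutamate carrier gene Slc25a22 at -1.98 (SE 0.11) and the aspartate aminotransferase genes Got2 at -1.84 (SE 0.08) and Got1 at -1.18 (SE 0.12). Of 12 GABA and glycine uptake and metabolism genes, 11 rose and 1 did not pass, with a median of 2.64 (camera, adjusted p = 3.3e-05; adjusted p = 0.118 with an estimated correlation). The GABA transporter gene Slc6a11 rose by 3.99 (SE 0.07). Of 21 ion, water and acid-base transport genes, 17 rose and 4 fell, with a median of 2.97 (camera, adjusted p = 5.3e-05; adjusted p = 0.110 with an estimated correlation). Kcnj10, the inward rectifier of potassium buffering, rose by 4.12 (SE 0.10), whereas the sodium-calcium exchanger gene Slc8a1 changed by -3.18 (SE 0.14). All 3 connexin genes rose, with a median of 3.97 set by Gjb6 (camera, adjusted p = 0.0366; adjusted p = 0.129 with an estimated correlation). These 4 lists hold 4, 1, 7 and 2 genes that also stand in other lists, so they are not independent of the marker list.

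Metabolic and lysosomal genes rose as well. Of 37 genes of glycogen, glycolysis and lactate handling, 32 rose, 4 fell and 1 did not pass, with a median of 2.06 (camera, adjusted p = 1.8e-06; adjusted p = 0.118 with an estimated correlation). The glycogen phosphorylase gene Pygb rose by 4.12 (SE 0.14) and Ldhb by 3.37 (SE 0.13), while the neuronal enolase gene Eno2, and the glucose transporter gene Slc2a3 changed by -3.25 (SE 0.08) and -3.00 (SE 0.16), and the lactate transporter gene Slc16a7 fell by more than either. Of 29 fatty acid oxidation genes, 25 rose and 4 fell, with a median of 3.57 (camera, adjusted p = 2.3e-07; adjusted p = 0.118 with an estimated correlation). Cpt1a, which admits fatty acids to mitochondria, rose by 3.59 (SE 0.07) and Acadvl by 4.12 (SE 0.09), whereas the acyl-CoA synthetase genes Acsl5, Acsl4 and Acsl1 changed by -2.47 (SE 0.08), -2.20 (SE 0.14) and -1.66 (SE 0.18). Of 25 cholesterol synthesis genes, 23 rose, 1 fell and 1 did not pass, with a median of 2.34 (camera, adjusted p = 3.2e-06; adjusted p = 0.268 with an estimated correlation). On the deposited scale 21 rose and 3 fell. Cyp51 rose by 3.46 (SE 0.11) and Hmgcs1 by 2.93 (SE 0.12); Ggps1, which feeds protein prenylation, changed by -1.38 (SE 0.09). Of 30 phagocytosis and lysosome genes, 24 rose, 5 fell and 1 did not pass, with a median of 2.05 (camera, adjusted p = 7.4e-06; adjusted p = 0.110 with an estimated correlation). The phagocytic receptor gene Mertk rose by 3.33 (SE 0.13) and Lamp1 by 2.79 (SE 0.08), and the proton pump gene Atp6v1b2 changed by -1.03 (SE 0.12). Of 34 secreted synapse and matrix factor genes, 21 rose, 12 fell and 1 did not pass, with a median of 2.50 (camera, adjusted p = 0.0181; adjusted p = 0.154 with an estimated correlation). Sparcl1 rose by 3.94 (SE 0.15) and Gpc4 by 2.40 (SE 0.13), against Nptx1 at -3.92 (SE 0.15), Tnr at -3.83 (SE 0.15) and Hapln4 at -3.48 (SE 0.24).

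The study's title also names calcium signals in astrocyte processes, and genes of calcium signalling divided. Of 63 tested, 22 rose, 39 fell and 2 did not pass, with a median of -1.31; on the deposited scale 13 rose and 45 fell. The inositol trisphosphate receptor genes moved apart: Itpr2 rose by 3.52 (SE 0.09), from 0.995 ± 0.0598 to 7.12 ± 0.313 FPKM, and Itpr1 changed by -4.05 (SE 0.08), from 79.6 ± 4.61 to 2.61 ± 0.216 FPKM. The phospholipase C genes Plcb3 and Plcd4 rose by 4.35 (SE 0.10) and 4.20 (SE 0.20), and the mitochondrial exchanger gene Slc8b1 by 4.01 (SE 0.13). The ryanodine receptor gene Ryr2 changed by -3.15 (SE 0.14) and the SERCA pump gene Atp2a2 by -0.28 (SE 0.07). As a set the list was lower (camera, adjusted p = 0.0168), a call lost with an estimated correlation (adjusted p = 0.253) and on the deposited scale (adjusted p = 0.119). Of 49 G protein-coupled receptor genes, 19 rose, 22 fell and 8 did not pass (camera, adjusted p = 0.798), and the median of 0.14 was opposite in sign to the mean of -0.16, to the test and to the median on the deposited scale. Gpr37l1 rose by 4.74 (SE 0.11), the neurotensin receptor gene Ntsr2 by 4.55 (SE 0.15), the metabotropic glutamate receptor gene Grm3 by 3.14 (SE 0.10) and the endothelin receptor gene Ednrb by 2.64 (SE 0.15). P2ry1, a purinergic receptor gene, had 0.11 (SE 0.25) and did not pass; its deposited FPKM was lower in HA IP in all 4 animals.

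Of 32 astroglial transcription factor genes, 31 rose and 1 did not pass, with a median of 3.10 and medians between 3.11 and 3.13 in the 4 animals (camera, adjusted p = 1.5e-10; adjusted p = 0.00857 with an estimated correlation). Sox9 rose by 4.68 (SE 0.10) and Nfia by 2.91 (SE 0.09), and 6 of the 32 also stand in other lists. Genes known to be induced in reactive astrocytes did not pass as a set: of 34, 13 rose, 4 fell and 17 did not pass (median 0.31, or -0.40 on the deposited scale; camera, adjusted p = 0.528). The balance was not stable: 9 were higher and 10 lower on the deposited scale, 14 and 11 without animal 581 or its HA IP library, and 14 and 7 with limma-voom. The intermediate filament genes Gfap and Vim rose by 4.79 (SE 0.43) and 3.90 (SE 0.45), and their levels differed widely between animals in HA IP (548 ± 357 and 142 ± 118 FPKM) and in input (34.8 ± 21.0 and 14.6 ± 6.42 FPKM). The log2 ratios within animals ran from 4.61 to 4.94 for Gfap and from 3.48 to 4.53 for Vim. The acute-phase gene Serpina3n rose by 1.77 (SE 0.31), while Ptgs2, the inducible cyclooxygenase gene, and Srgn changed by -3.98 (SE 0.28) and -1.86 (SE 0.30). The list median ran from -0.28 in animal 579 to 0.94 in animal 581.

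Lists that bear on RNA class gave mixed results. Of 11 nuclear-retained long noncoding RNAs, 8 were lower, 1 higher and 2 not called, with a median of -1.84 (camera, adjusted p = 0.0207). The call was lost with an estimated correlation (adjusted p = 0.354) and on the deposited scale (adjusted p = 0.111). The list median was -1.34 in animal 595 and between -1.99 and -1.97 in the other animals. Meg3 changed by -1.90 (SE 0.20) and Neat1 by -1.02 (SE 0.16), and Pantr1 rose by 2.73 (SE 0.19). Malat1 had -0.12 (SE 0.28) and did not pass; without the HA IP library of animal 595 it was -0.43, and without that animal -0.53, and it then passed, as it did at -0.96 on the deposited scale with all libraries. Of 81 cytosolic ribosomal protein genes, 24 rose, 24 fell and 33 did not pass, or 20 and 20 adjusted over the list alone (median 0.13, or -0.71 on the deposited scale; camera, adjusted p = 0.887). On the deposited scale 5 were higher and 51 lower. Higher and lower numbered 18 and 10 without animal 579, 15 and 26 without 581, 33 and 19 without 595, 20 and 15 without the input of 579, and 24 and 15 without the input of 580. Rpl17, Rps12 and Rpl32 changed by -1.50 (SE 0.24), -1.43 (SE 0.29) and -1.26 (SE 0.25); ribosomal protein genes have many processed pseudogenes, so their values are uncertain. Of 76 nuclear-encoded respiratory chain genes, 68 rose, 1 fell and 7 did not pass, with a median of 1.25 (camera, adjusted p = 1.0e-08; adjusted p = 0.432 with an estimated correlation), but on the deposited scale 41 rose and 12 fell, and with the animal as a block 69 and 3. Atp5b rose by 1.74 (SE 0.12), and Cox4i1 had 0.84 (SE 0.17), which was -0.01 without the scaling and did not pass there. Of 16 replication-dependent histone genes, 12 rose, 3 fell and 1 did not pass, with a median of 1.89. This list missed the threshold (camera, adjusted p = 0.0546; adjusted p = 0.508 with an estimated correlation) and passed it with the animal as a block (adjusted p = 0.0175) and on the deposited scale (adjusted p = 0.00208). Without a filter 23 members rose and 6 fell, with a filter of 1 CPM 8 and 1, and without the HA IP library of animal 595 12 and 5. Hist1h1c rose by 3.51 (SE 0.30), while Hist3h2ba changed by -2.59 (SE 0.13).

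Of the 33 lists, 12 were called higher, 12 lower and 9 not called, and 7 of the 24 calls held with an estimated correlation. Adjusted over the list alone, the numbers of members that rose and fell were those given above for every list except the ependymal and ribosomal protein lists. Fold changes are on the log2(FPKM + 0.1) scale and understate the change of genes at low FPKM, such as Kcnk9 in HA IP, or Dcx, which averaged 0.107 FPKM in HA IP and 0.912 FPKM in input after TMM scaling.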

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

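The tests of explanations in this part were chosen after the values they bear on had been seen, and for 2 of them the measure was replaced, in 1 case more than once, as stated below. Of 229 values examined over the 4 animals or the 4 libraries of a group, 25 had a sample far from the other 3 by Dixon's ratio of gap to range. Chance gives about 1 in 20 such values, and the values are not independent of each other. Animal 595 was the distant sample in 16 of them, and animals 579, 580 and 581 in 1, 4 and 4. The 16 include its depth and its Xist and Y-linked reads in both groups, which are not 16 separate differences in enrichment.

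Animal 595 differed in depth in both groups, with 33.8 M fragments (M for 1e6) in HA IP against at least 44.3 M in the others and 53.6 M in input against at most 37.0 M. It was the animal with Xist reads, 252 CPM in HA IP and 124 CPM in input, and its summed Y-linked reads were 0.325 CPM and 0 CPM against at least 73.8 CPM and 113 CPM in the others. These reads set animal 595 apart from the others by sex, so its other differences cannot be told apart from an effect of sex. In log2 ratios of HA IP to input it stood above the others for Mgp (-2.33), Ccdc153 (-1.02), Slc2a3 (-2.72) and Hist1h1c (3.66), and below them for Dhcr7 (2.68) and for the median of the GABA and glycine list (2.59). Ccdc153 averaged 0.0572 CPM in HA IP, with an FPKM below the pseudocount, so its ratio rests on few fragments. Animal 581 stood above the others in Olig2 (3.17), Jun (2.35) and Ndufa4 (-0.0621), and below them in Pdgfrb (2.02). Animal 580 stood above the others in Gjb6 (4.08), which sets the connexin list median (4.08), and below them in Dlg4 (-2.44) and in the median of the inhibitory neuron list (-3.24). Animal 579 had the lowest median of the immediate early genes (-2.52, others -2.41 to -2.39).

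Nuclear-retained RNAs were higher in the HA IP library of animal 595: the log2 ratio was 1.14 for Malat1 (others -0.68 to -0.39), -0.73 for Neat1 (others -1.13 to -1.08), -1.35 for Meg3 (others -2.12 to -2.06) and -1.34 for the list median (others -1.99 to -1.97). More lysate RNA carried over into that library would raise neuronal transcripts by as many percentage points of input. Yet the pan-neuronal median rose by 0.608 points and the nuclear-retained median by 9.12, that is, by 6.67% as much. The oligodendrocyte median rose by more, 3.06 points or 33.6% as much, the endothelial by 0.509, and the microglia median changed by -0.0792. Oligodendrocyte and endothelial markers were not higher in that HA IP library (log2 -0.05 and -0.01 against the others). They were lower in its input (-0.34 and -0.31), so their rises in percent of input came with lower inputs. Together the medians speak against carry-over as the whole source of the difference. A gene length trend among the HA IP libraries accounted for little, since 90.0% of the list's difference of 0.87 was left (0.79) after it was removed. More nuclear RNA in that preparation is a possible explanation that was not tested, and no biological explanation was tested.

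Transcripts of the fibroblast and meningeal list differed between HA IP libraries, with a median ratio to input in CPM of 0.301, 0.586 and 0.319 in animals 579, 580 and 581 and of 1.27 in animal 595. Carried-over lysate RNA cannot lift a transcript above its input, but a bootstrap of the list median over its 15 members (2000 draws) was borderline in animal 595, with an interval from 1.0004 to 3.74, and the count that replaced it, 8 of the 13 members that were not above their input in all 4 animals, allowed for counting error only. In the third test 2 of the 13, Aldh1a2 at 3.93 and Crabp2 at 3.74 times input, lay above it by more than 2.88-fold. This bound came from how far animal 595 lay from the others over 13100 genes in no list. It measures a difference between animals, not the distance of a ratio from 1, and includes real differences of that animal. It is therefore not a measure of noise alone. The test required 3 such members, a number set after the count of 8 had been seen. With fewer than that, this count did not decide between carry-over and another source. The list medians, at least 0.301 times input (lowest bootstrap bound 0.158), argue against evenly carried-over lysate RNA as their whole source. Pan-neuronal, oligodendrocyte, microglia and endothelial medians were at most 10.6% of input CPM in any animal, and the pan-neuronal median rose by 0.608 points in animal 595. Single members, such as Mgp at 0.114 times input in animal 595, lay near those shares. Carry-over that favours some transcripts was not tested. Different amounts of meninges in the dissected cortex would move the inputs along with the HA IP libraries, but the list median moved over the inputs by 12.97% of its range over the HA IP libraries (0.23 against 1.74 in log2). Single members moved in opposite directions in the input of animal 581, with Col3a1 at 19.7 CPM (others 3.77 to 6.50) and Ogn at 6.49 CPM (others 12.4 to 15.3). The median therefore bears only on a shift of the list as a whole, not on differences in composition. Recombination in meningeal cells that differs between animals is a possible explanation that was not tested.

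Markers of other cell types were still read in HA IP, at a median of 6.91 ± 0.328% of input CPM for pan-neuronal, 6.42 ± 0.179% for microglia, 7.98 ± 1.56% for oligodendrocyte and 9.85 ± 0.978% for endothelial markers (SD, n = 4 animals; members with at least 1 CPM in input). With 1 share of lysate RNA carried over these would lie close together, and the endothelial was 1.535 times the microglia median, over the limit of 1.5 in 3 animals and under it, at 1.35, in animal 580, so 1 share and several sources cannot be told apart at this margin. This was the second measure tried, since medians of the fitted ratios, seen first, include the pseudocount and the TMM scaling; they gave 24.2% for endothelial and 12.6% for pan-neuronal markers, 1.92-fold apart. A further test, with a limit of 2-fold, was set after the spread within the pan-neuronal list had been seen: its upper and lower quartiles differed by 2.35-fold to 2.96-fold in the 4 animals, with Cplx2 highest at 33.1% of input, which speaks against evenly carried-over lysate RNA as the whole source of these reads. Low expression in the tagged cells and carry-over that favours some transcripts were not tested.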

How the results depend on the processing

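The pseudocounts of 0.01 and 1, limma's treat and the length trend were chosen after the data were seen, the other settings before. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, called as many genes as the 6573 higher or the 6413 lower, and the highest of the others called 0 (limma; 0 with voom). These splits ignore the pairing, and the others put the difference between HA IP and input into the residual, which lowers their counts. At an unadjusted p under 0.05 the other splits had 7 to 972 genes and the real one 13126; the 8 splits that part all 4 animal pairs are too few for a share under 0.05, and the highest of the others among them had 359. After removal of the length trend 90.9% of the calls at 2-fold were left on their side, with and without the replicate block. On the deposited scale 3643 genes were higher, and 1908 and 6723 were at least 2-fold higher and lower, because every ratio is lowered there; 1034 called genes passed on the other side, and 0 of those called at 2-fold. Medians of the respiratory chain (0.41), glycogen (1.21), lysosome (1.20) and cholesterol lists (1.4998) fell there by over 1.5 times, all still called. With a pseudocount of 1, which shrinks low genes, 2445 were at least 2-fold lower, and the medians of called lists that moved by about 1.5 times or more were microglia (-1.97), endothelial (-0.85), oligodendrocyte (-1.57) and calcium (-0.62), all still called. These numbers over all genes moved by over 1.5 times under no other setting run. Examples of numbers within lists that did are given with the lists, but not all of them. With median-of-ratios scaling, for example, 2 cholesterol synthesis genes and 1 astroglial transcription factor gene were lower, against 1 and 0 in the main fit. With an animal left out 6222 to 6528 genes were higher and 5975 to 6360 lower. The replicate block gave 6727 and 6579, passed the histone list (1.89), Lcn2, Rplp0 and Ndufa4, and changed no other call of a list or named gene. Depth limits which genes could be tested (15605 of 20045 detected); thinning to the smallest library gave 6509 higher and 6355 lower, and lower depths were not tried.

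List calls were lost on the deposited scale for calcium signalling (-2.07), immediate early genes (-3.24) and nuclear-retained RNAs (-2.68), and Fezf2 (-0.45) and Adra1a (0.32 with TMM, uncalled; -0.43) reversed there. The histone list passed on that scale (1.29), with median-of-ratios scaling (1.83), without a filter (0.52), without animal 580 or 581, without the input of 579, 580 or 581 and without the HA IP of 581; over all leave-outs, passing or not, it ran from 1.44 to 2.38, and the cause was not tested. With an estimated correlation, at unchanged medians, calls were lost for excitatory neuron (-3.49), oligodendrocyte (-2.57), endothelial (-2.05), glutamate (3.55), GABA (2.64), ion transport (2.97), connexin (3.97), calcium (-1.31), glycogen (2.06), cholesterol (2.34), fatty acid (3.57), secreted factor (2.50), postsynaptic (-2.28), immediate early (-2.44), lysosome (2.05), nuclear-retained (-1.84) and respiratory chain genes (1.25). Fry, which does not compare a list with other genes, passed the precursor (-0.82), mural (-0.77), ependymal (0.98), progenitor (0.83) and histone lists (1.89) in its directional and mixed forms, and in the mixed form only the fibroblast (-0.16), receptor (0.14), reactive (0.31) and ribosomal protein lists (0.13). Of the planned tests, limma-voom ran on the recovered fragments (6588 higher, 6456 lower). The planned test for raw counts was run neither on the deposited FPKM nor on the recovered fragments.

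Single libraries decided some named genes. Dcn (-1.12) was no longer called without animal 579 (-0.77) or 581 (-0.93), or without the input (-1.03) or HA IP (-0.88) of 579. Cox7b (-0.42) was lost without animal 579 (-0.42) or its input (-0.42) or HA IP (-0.44), the input of 580 (-0.30) or the HA IP of 595 (-0.33), Thbs1 (-0.82) without animal 579 (-0.65), and Best1 (-0.59) without 580 (-0.41) or 581 (-0.58). Lcn2 (-1.03) passed without animal 595 (-1.55) or its input (-1.68), Rplp0 (0.47, but lower in HA IP in deposited FPKM in 3 of 4 animals) without 595 (0.66) or its HA IP (0.71), and Adra1a without 581 (0.40) or its input (0.45) and with voom (0.37). Ndufa4 (-0.38) passed with median-of-ratios scaling (-0.47), voom (-0.38) and on the deposited scale (-1.22), where Rps6 (-0.04) at -0.88 and Col1a1 (-0.03) at -0.84 passed and Grin3a (0.57) at -0.26 was lost.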

Other observations

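The groups and genes in this part were chosen after their values were seen, and no explanation for them was tested. Besides the contrast of HA IP with input, several gene lists differed between animals. Immediate early genes, which respond to neuronal activity, had a median 0.70 above the other 3 inputs (log2) in the input of animal 580 and 0.68 above the other HA IP libraries in its HA IP, while in animal 595 the medians were -0.60 and -0.68 relative to the others. Reactive astrocyte genes stood 0.54 above the others in the HA IP of animal 581 and 0.17 above in its input. Cytosolic ribosomal protein genes stood 0.58 above the others in the HA IP of animal 581 and at -0.75 in that of animal 595, while the inputs of these animals stood at -0.23 and -0.22.

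In the HA IP library of animal 595, several genes stood above the other 3 HA IP libraries and differed less between the inputs. Ppp1r9a, which encodes the actin-binding protein neurabin, had 599 CPM there and a mean of 39.5 CPM in the other HA IP libraries, and the spectrin gene Sptan1 had 1805 CPM against 221. The log2 difference was 3.33 for Sptb, 3.26 for Actn2, 3.06 for Dbn1, 2.83 for Fbxo34, 2.75 for Sptbn1, 2.59 for Ogn, 2.50 for Myo5a, 2.36 for Myh10, 2.23 for Spp1 and 2.12 for Fkbp5. In the input of animal 595 these genes differed from the other inputs by -0.02 (Sptb) to 0.65 (Fkbp5). They are examples from the 20 genes with the largest such differences, and no gene group was tested for enrichment among them.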
